A study of Cavia porcellus with 14 samples.

How the data were processed

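DNA methylation was measured by reduced representation bisulfite sequencing (RRBS), in which DNA fragments rich in CpG are selected and unmethylated cytosines are converted before sequencing. The DNA came from dried spots of whole blood of newborn female guinea pigs (Cavia porcellus). Their mothers had received betamethasone, a synthetic glucocorticoid, or saline on gestational days 50 and 51. Each treatment had 7 animals, 14 in all, and every animal was placed in its group by its sample title.

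Per the submitters' processing notes, the tools were Trim Galore, Bismark 0.16.0, Bowtie2 2.3.4.3 and SAMtools 1.9. Those notes give no order or settings. The genome build, the tool and model of the differential test, and the filters are not given in the sources used here.

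The authors deposited a table of 6017 cytosine positions on 152 scaffolds as the result of their comparison. The deposited coverage (signal) is the number of reads at a position in each group, with no value per animal. The deposited methylated read counts are whole numbers, also 1 per group. The authors' fraction (beta value) is the methylated count divided by the coverage. The authors' difference is the case level minus the control level in percentage points. Saline is named as the control in the series design, so the case columns were read as betamethasone. Levels and differences were recomputed from the counts and matched at every position within 1e-05 percentage points. The deposited table gives 2 p-values and a false discovery rate per position, and no source used here says how the p-values differ. The deposited second p-value took 1846 distinct values over the 6017 positions. The false discovery rate was under 0.05 throughout, the highest being 0.04999. For the 2496 positions with a second p-value above 1e-05, rate × rank / second p-value gave a median of 2930000, with a range from 2910000 to 2960000 (to the nearest 10000). This is the number of tests that a Benjamini-Hochberg adjustment would imply.

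The lowest coverage was 10 reads in each group. Median coverage was 125 reads in the betamethasone pool (quartiles 51 and 224) and 121 in the saline pool (quartiles 50 and 209). Because the reads of a group are summed, no spread between animals can be computed. Intervals of methylation levels and of their differences cover counting error of reads only, and reads without molecular identifiers are not independent molecules. Intervals of shares of clusters or of pairs of positions cover the number of clusters or pairs, which all come from the same 2 pools. All are 95% intervals, exact (Clopper-Pearson) for a share and Newcombe's for a difference between shares.

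Listed positions less than 1000 bp apart on a scaffold were joined into clusters, and a cluster's difference is the mean over its positions. The share of clusters with higher methylation was compared with 50% by an exact two-sided binomial test. The sizes of higher and lower clusters were compared by a two-sided permutation test of the medians (100000 resamples, or 20000 where every position was its own cluster). The share of neighbouring listed positions with the same direction was compared with 10000 shuffles of the signs over positions. These choices, and the rule that the 5 positions with the largest positive and the 5 with the largest negative difference are named where no gene annotation can be used, were fixed before the data were examined. Regions of 5 or more listed positions that all went one way were chosen for naming after their values had been seen. A two-sided Fisher's exact test of methylated against unmethylated reads was run per position, with Benjamini-Hochberg adjustment over the 6017 positions. It compares 2 pools of reads, not 7 animals with 7, and the positions it was run on had been selected for a difference on the same reads. The adjustment was therefore also made over the 2930000 implied tests. Read sampling was described by 1000 draws of methylated reads at the deposited coverages, with both groups given the level of the combined reads. The draws apply no selection of positions, unlike the list.

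The scripts were tested on simulated data at the 6017 positions and their coverages, with 200 positions changed per run. Fisher's exact test recovered 26.5%, 62.5% and 74.5% of changes of 10, 20 and 30 percentage points, with 1, 2 and 4 false calls. The simulated reads held no variation between animals and no selection of positions. The false calls therefore cover read sampling only. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9 were used.

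Alternatives were a larger minimum difference, a lower false discovery rate, other cluster distances, a first p-value under 0.05, at least 50 reads in both groups, and leaving out a dense block of positions. Planned comparisons of promoters, exons, introns, CpG islands, scaffolds, glucocorticoid response elements and 12 gene lists needed a genome or annotation in the coordinates of the table and were not run. The gene table used here places no gene on a scaffold of the deposited table, so no gene was assigned to a position. The sequence context of the positions was not checked for the same reason, and they are called positions throughout.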

Results

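Betamethasone is given to pregnant women at risk of preterm birth to mature the fetal lung. The series asked whether exposure before birth leaves a methylation signature in the blood of the newborn. Whole-blood DNA from 7 female guinea pig offspring of betamethasone-treated mothers was compared with that of 7 offspring of saline-treated mothers. The authors' deposited table lists 6017 positions that passed a false discovery rate of 0.05 in this comparison. Over these positions 864465 reads were summed in the betamethasone group and 815967 in the saline group. Positions are given as scaffold and coordinate as deposited, with a genome build that is not given in the sources used here, and no gene could be assigned to them.

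Methylation after betamethasone was higher at 3132 of the listed positions, lower at 2846 and equal at 39. The listed positions fell into 820 clusters, of which 460 were higher, 358 lower and 2 without a difference. Higher clusters thus made up 56.2% (95% exact interval 52.8 to 59.7) of those with a difference, more than an even split (exact two-sided binomial test, p = 0.00041). All clusters were measured in the same 2 pools of animals, so the test covers the spread between clusters and not that between animals. The split was 49.5% among the 194 clusters left at a false discovery rate of 0.001 or less (exact binomial test, p = 0.94), so it was not seen in the most stringent part of the list. The mean level over the listed positions was 61.1% after betamethasone and 60.6% after saline, a difference of 0.54 percentage points.

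Differences were small at most positions. The median absolute difference was 2.44 percentage points, and 75% of positions differed by 5.49 points or less. A difference of 10 points or more was present at 622 positions (360 higher, 262 lower), which is 10.3% of the list. A difference of 20 points or more was present at 113 positions (70 higher, 43 lower). Read sampling with no difference between the groups gave a median of 2.07 points (range 1.96 to 2.19 over 1000 draws) and 441 positions with 10 points or more (range 389 to 496). The observed values were above these ranges, but the listed positions had been selected for a difference and the draws had not, so the comparison does not exclude read sampling. Higher clusters had a median difference of 1.89 points and lower clusters one of 1.57 points in size. These sizes did not differ beyond the spread between clusters (difference 0.31 points, permutation test, p = 0.094). With clusters under 100 bp the difference was 0.62 points (permutation test, p = 8e-05), and with every position counted it was 0.43 points (p = 5e-05, the smallest that the permutations can give).

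**Figure D1:**
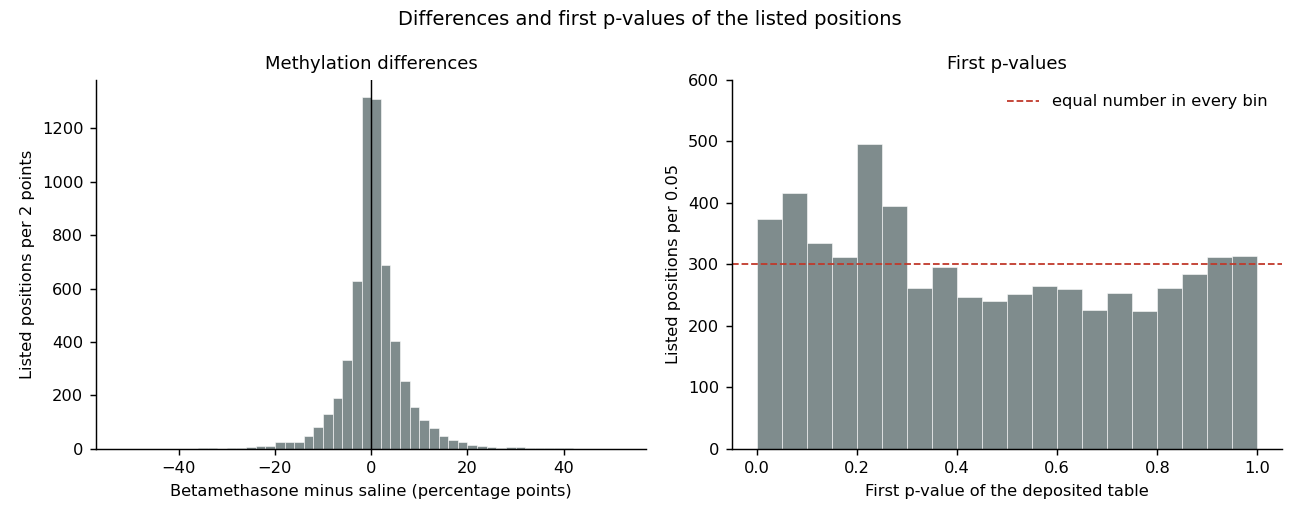
The left panel counts listed positions by methylation difference (betamethasone minus saline, percentage points), and the right panel by the first p-value of the deposited table, with a dashed line for an equal number in every bin. Most differences lie near 0, and 373 of the 6017 first p-values are under 0.05.

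The 5 largest positive differences were at positions with 10 to 35 reads per group. On scaffold 30 at 2132889 methylation was 95.7% in 23 betamethasone reads and 45.5% in 11 saline reads, a difference of 50.2 points (interval 18.9 to 74.6). On scaffold 111 at 3734856 9 of 10 betamethasone reads were methylated against 6 of 13 saline reads, a difference of 43.8 points (interval 4.66 to 68.2). On scaffold 25 at 17470029 it was 62.9% in 35 reads against 21.1% in 19, a difference of 41.8 points (interval 14.1 to 60.6). On scaffold 111 at 3807915, 5 of 12 betamethasone reads and 0 of 12 saline reads were methylated. The exact upper limit of that saline level was 26.5%. On scaffold 111 at 3864605 all 12 betamethasone reads were methylated, against 61.1% of 18 saline reads. None of these 5 positions passed Fisher's exact test on the pooled reads after adjustment over the list (lowest adjusted p = 0.25).

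The largest negative difference was on scaffold 159 at 642117, where methylation was 23.1% in 13 betamethasone reads and 69.2% in 13 saline reads. The difference was -46.2 points (interval -69.6 to -7.94), and the position did not pass the adjusted Fisher's exact test (adjusted p = 0.82). On scaffold 25 at 27900119 methylation was 9.09% in 132 betamethasone reads and 45.7% in 94 saline reads, a difference of -36.7 points (interval -47.4 to -25.2). This was the position with the lowest Fisher's exact p on pooled reads (adjusted over the list, p = 2.9e-06), while its first p-value in the authors' deposited table was 0.16. Its cluster of 4 positions, from 27900113 to 27900141, held 1 higher and 3 lower, at -13.8 ± 18.1 points (SD over positions). No other position of that cluster passed the adjusted Fisher's exact test, and none had a first p-value under 0.05. The other 3 negative differences named by the rule were -34.9 points on scaffold 171 at 465620, -34.7 points on scaffold 62 at 5713113 and -33.3 points on scaffold 75 at 2639923. These rested on 10 to 18 reads per group, and the interval at the position on scaffold 62 reached from -61.0 to 3.60 points. None of the 3 passed the adjusted Fisher's exact test (lowest adjusted p = 0.77).

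Neighbouring positions went the same way more often than shuffled signs did. Of 5160 pairs of neighbouring listed positions less than 1000 bp apart, 53.9% had the same direction, against 50.1% with shuffled signs (permutation test, p = 0.0001, the smallest that the shuffles can give). Of 381 regions with 5 or more listed positions, 22 went one way throughout, 16 higher and 6 lower, and 359 held both directions. Shuffled signs gave 6.80 one-way regions on average and 15 at most in 1000 shuffles. Positions in a region share reads and animals, so they are not independent measurements. Isolated pairs 1 bp apart had the same direction in 50.9% of 888 (exact binomial test, p = 0.61). That share was 70.7% of 75 where the first position differed by 10 points or more.

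The one-way region with the most positions spanned 193 bp of scaffold 10, from 28071722 to 28071914. Methylation was lower after betamethasone at all of its 22 positions, by 15.3 ± 6.45 points (SD over positions), from a mean level of 74.9% to 59.5%. Coverage there was 42 to 272 reads in the betamethasone pool and 33 to 215 in the saline pool. Of its positions, 7 passed the adjusted Fisher's exact test and 7 had a first p-value under 0.05. A further lower region of 5 positions lay on scaffold 101 from 1948837 to 1948871, at 48.2% against 57.7%, with 525 to 541 reads per position in either pool. It differed by -9.52 ± 1.33 points (SD over positions), and 3 of its first p-values were under 0.05, while none of its positions passed the adjusted Fisher's exact test.

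Methylation after betamethasone was higher throughout in 16 regions. On scaffold 10, from 40025233 to 40025401, 9 of 9 positions were higher, with a mean level of 23.9% against 11.3% and a difference of 12.6 ± 5.66 points (SD over positions). Of these, 7 had a first p-value under 0.05 and 3 passed the adjusted Fisher's exact test. On scaffold 1, from 71093567 to 71093690, 10 of 10 positions were higher, at 28.7% against 17.4%, and 2 passed the adjusted Fisher's exact test. On scaffold 13, from 1743630 to 1743938, the mean level over 10 positions was 42.8% against 26.3%, with 12 to 188 reads per position. Of those positions, 3 had a first p-value under 0.05 and none passed the adjusted Fisher's exact test. On scaffold 25, from 16805089 to 16805309, it was 83.5% against 67.9% over 5 positions, with 25 to 30 betamethasone reads and 11 to 48 saline reads. None of these passed the adjusted Fisher's exact test. The region with the largest mean difference was on scaffold 1 from 53415017 to 53415075, at 67.9% against 34.7% over 5 positions, a difference of 33.2 ± 5.51 points (SD over positions). It rested on 17 to 20 betamethasone reads and 32 to 33 saline reads per position, and none of its positions passed the adjusted Fisher's exact test.

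**Figure D2:**
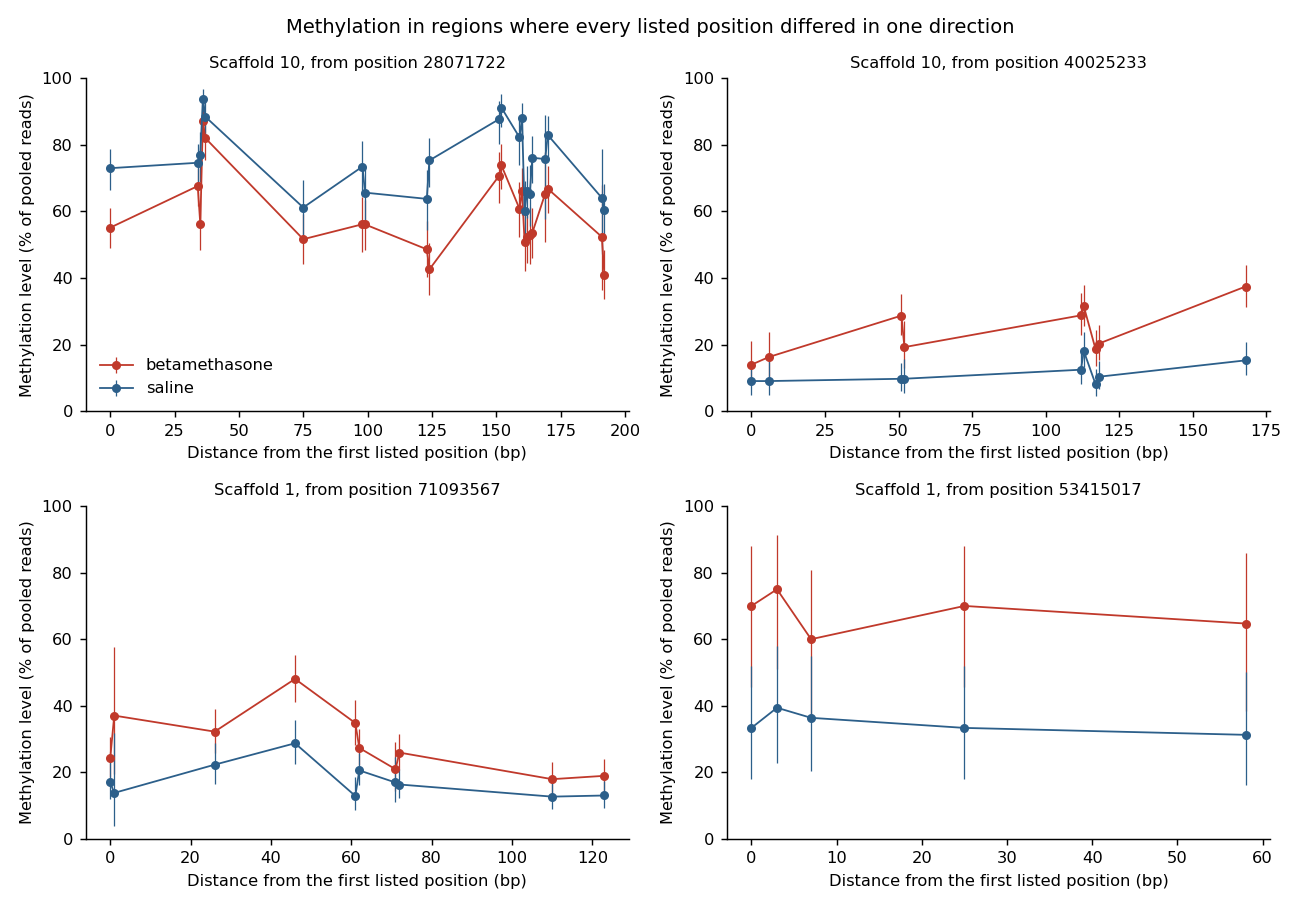
Methylation level (% of pooled reads) of the betamethasone (red) and saline (blue) groups at each listed position of 4 regions, by distance in bp from the first position; bars are 95% exact intervals for counting error. Betamethasone lies below saline at all 22 positions of the scaffold 10 region from 28071722 and above it in the other regions, with the widest intervals in the scaffold 1 region from 53415017.

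Few of the listed positions passed by the first p-value or by Fisher's exact test. In the authors' deposited table the first p-value was under 0.05 at 373 positions (215 higher, 158 lower), or 6.20% of the list, with a median of 0.43 and a lowest value of 0.00014. After Benjamini-Hochberg adjustment of the first p-values over the listed positions, none was under 0.05. Fisher's exact test on pooled reads gave 362 positions at an unadjusted p under 0.05 and 24 after adjustment over the list, 15 higher and 9 lower. The list had already been selected for a difference on the same reads, so this adjustment is lenient. Adjusted over the 2930000 tests implied by the false discovery rates, 2 positions passed, 27900119 on scaffold 25 and 28071846 on scaffold 10. These 24 positions lay in 12 clusters, and 15 of them in the one-way regions. Besides regions already named, they included 3 of 7 positions on scaffold 1 from 42827484 to 42827565. They also included 2 of 4 positions on scaffold 10 from 39303766 to 39303938, where all 4 were higher, at a mean of 56.5% against 37.6%.

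Listed positions were concentrated on scaffold 111, which held 1279 of them, 21.3% of the list. Scaffold 62 came next with 230 positions. On scaffold 111, 1272 positions lay in a block of 206 kb from 3734774 to 3941117, in 47 clusters. Of these, 675 were higher after betamethasone and 589 lower, and the median absolute difference was 2.36 points against 2.48 points elsewhere. By cluster, the whole list held 460 higher and 358 lower, and without the block 426 higher and 345 lower. Most clusters of the block were therefore higher, which was not tested. The median false discovery rate was 1.2e-07 in the block and 0.0090 elsewhere in the authors' deposited table, while 5.35% of first p-values in the block and 6.43% elsewhere were under 0.05. A false discovery rate of exactly 0 was deposited for 232 positions in the block and 38 elsewhere. The cluster with the most positions, 122 from 3793789 to 3802275, had 75 higher and 46 lower, with a mean level of 69.9% against 68.6%.

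**Figure D3:**
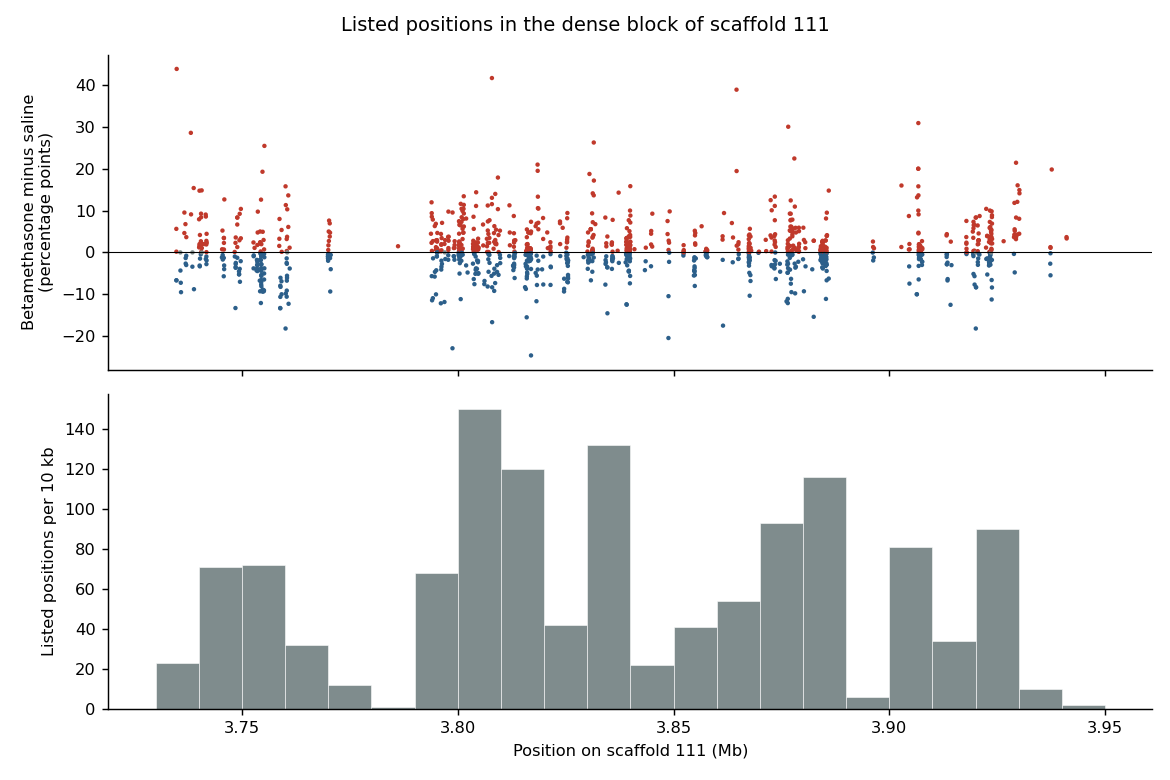
Upper panel, methylation difference (betamethasone minus saline, percentage points) at each of the 1272 listed positions in the block of scaffold 111 (red above 0, blue below 0, grey at 0); lower panel, listed positions per 10 kb. Both directions are interleaved along the block, with 675 positions higher and 589 lower.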

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

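The list of 6017 positions shrank to 622 with a minimum difference of 10 points, to 113 with 20 points, to 3632 at a false discovery rate of 0.01 and to 2465 at 0.001. Among alternatives chosen after the data were seen, 373 positions had a first p-value under 0.05 and 24 passed Fisher's exact test on pooled reads adjusted over the list, or 2 adjusted over the implied number of tests. The share of higher clusters stayed above 50% with a p under the threshold in 9 of 10 alternatives, and was 49.5% at a false discovery rate of 0.001; the cause was not tested. The median size of higher clusters exceeded that of lower ones past the threshold in 3 of 8 alternatives. The excess was 0.43 points with every position counted, 0.62 with clusters under 100 bp and 0.37 with at least 50 reads, against 0.31 in the main setting; the cause was not tested. The excess of neighbours with the same direction held in 9 of 9 alternatives. No paired analysis was possible because the table holds 1 value per group and none per animal. For the same reason no animal could be left out and no other split of the 14 animals could be fitted. The planned coverage minimums of 5 and 20 reads per animal, and limma on levels per animal, were not run, nor were the alternatives that need a genome. Depth limits single positions: with these coverages Fisher's exact test recovered 26.5% of simulated changes of 10 points.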

Other observations

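Tests named here were chosen after the result was seen, except the size of differences in the dense block and the count of large differences at well-covered positions, which were set before their values were looked at.

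Grouped by the mean level of both groups, 1695 listed positions were low (under 20%), 1040 intermediate and 3282 high (over 80%). At intermediate positions methylation was higher after betamethasone in 222 clusters and lower in 143, or 60.8% (exact binomial test, p = 4.2e-05, adjusted over 3 classes 0.00013), with mean levels of 58.0% against 55.9%. By the same exact test the share was 55.9% at low positions (adjusted p = 0.10) and 52.1% at high positions (adjusted p = 0.34). Because a cluster can hold positions of several classes, each cluster was also put in 1 class by its mean level. By this count 63.5% of intermediate and 52.5% of high clusters were higher (Fisher's exact test of the difference, p = 0.012). All clusters come from the same 2 pools of animals. The intermediate share was 59.1% without the dense block, 61.2% at 50 reads or more in both groups and 59.8% at a false discovery rate of 0.001 or less.

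A pair of positions 1 bp apart can be the opposite strands of the same CpG, although the sequence was not checked. Among 888 isolated pairs of this kind with differences other than 0, saline levels correlated across positions with r = 0.90, and 50.9% of pairs had the same direction (95% exact interval 47.6 to 54.2, exact binomial test, p = 0.61). The differences themselves correlated with r = 0.24 across these pairs. Where the first position differed by 5 points or more, 64.0% of 222 pairs had the same direction (exact binomial test, p = 3.8e-05). Where the first position differed by 10 points or more, 70.7% of 75 pairs had the same direction (interval 59.0 to 80.6, exact binomial test, p = 0.00045). Positions are not independent replicates, and they share animals.

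Most listed positions had an unremarkable first p-value, with 6.20% under 0.05. The first p-values were not spread evenly, however. Bins of width 0.05 held 416 positions from 0.05 and 495 from 0.2, against 240 from 0.45 and 314 from 0.95. A plain combination of the first p-values of listed neighbours is argued against as the origin of the second p-value at most positions. At most 2.08% of positions reached a combined value under 1e-04 by Stouffer's or Fisher's method in windows of 200, 1000 and 10000 bp. The highest second p-value was 0.0001. These combinations held no term for correlation between neighbours. Neighbours did share second p-values, such as 6.45e-06 from 71093567 to 71093690 on scaffold 1. Other ways of combining positions therefore stay open. Read sampling stays open for the list as a whole. The median absolute difference of 2.44 points exceeded the highest of 1000 draws, 2.19 points. However, the list was selected for a difference and the draws were not. Counting error of independent reads is argued against only at the 2 positions that passed Fisher's exact test adjusted over the 2930000 implied tests. Unlisted neighbours may still enter the second p-value, and variation between animals cannot be told apart from a treatment effect because reads are pooled; a treatment effect shared by small differences stays open and untested.

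The block on scaffold 111 held 21.1% of the list. Its clusters did not differ detectably in size from the others (median absolute difference -0.26 points relative to elsewhere, permutation test, p = 0.49). Nor did they differ detectably in saline coverage (-15.5 reads, permutation test, p = 0.54). The comparison of size is uneven, because a cluster's difference is a mean over its positions. The block held 1272 positions in 47 clusters, against 4745 in 773 elsewhere. Averaging more positions of both directions brings a mean nearer to no difference, so the size test cannot exclude larger differences in the block. Counted per position, median coverage in the block and elsewhere was 135.5 and 123 reads in the betamethasone pool. In the saline pool it was 122 and 121 reads. Betamethasone coverage was not tested. Neither larger treatment differences nor deeper coverage can be told apart from no difference with 47 clusters. The second p-value fell as the number of listed positions within 10000 bp rose (Spearman's rho = -0.70 across positions), but the second p-value itself sets which positions are listed, so this relation decides nothing. A hypothesis that could be tested with the full table of tested positions is that density of positions, rather than size of difference, sets the block apart.

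Differences of 20 points or more split by depth. At positions with fewer than 50 reads in a group there were 93, within the range of 52 to 103 that read sampling gave, so sampling may account for their number. At positions with 50 reads or more in both groups there were 20, against 9 at most in 1000 draws. That excess does not exclude read sampling, because the positions had been selected for a difference and the draws had not. Of these, 27900119 on scaffold 25 and 28071846 on scaffold 10 passed Fisher's exact test on pooled reads adjusted over the 2930000 implied tests. Their unadjusted p-values by that test were 4.8e-10 and 8.5e-09. These values argue against counting error of independent reads at those 2 positions, but reads without molecular identifiers are not independent molecules. For the 20 as a set, sampling, treatment and single animals with many reads cannot be told apart with pooled reads. The median of the lower coverage was 18 reads at differences of 20 points or more and 118 reads below.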
